A study of Mus musculus with 6 samples.

How the data were processed

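RNA from 6 samples of RAW 264.7 cells, a mouse macrophage line, was sequenced after the cells had been stimulated with lipopolysaccharide and then given extracellular vesicles of tendon stem cells. In 3 samples the vesicles came from tendon stem cells kept in normoxia (normoxic-EV) and in 3 from tendon stem cells preconditioned in hypoxia (hypoxic-EV). Groups were taken from the treatment given for each sample in the labels. The labels do not say whether the samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The species of the tendon stem cells is not given in the sources used here. Cells without vesicles were not analysed here, so each value compares the vesicle treatments with each other and not with untreated cells.

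Per the labels' protocols, RNA was extracted with a column kit, poly(A) RNA was enriched, and TruSeq libraries were read in pairs on an Illumina HiSeq instrument. The submitters' processing notes name HISAT2, featureCounts, DESeq2 and the mouse build GRCm39. Their versions, the gene annotation, the strand setting and the treatment of multi-mapping reads are not given in the sources used here. Reads of overlapping genes on opposite strands, and of near-identical copies, therefore cannot be assigned with certainty. The authors deposited whole-number counts per gene for 57010 genes, of which 26398 had at least 1 count. They also deposited FPKM values, and for each of those 26398 genes the FPKM equalled the count divided by the library total and by a length that was the same in all 6 libraries within a relative tolerance of 1e-06. A deposited table of normalized counts, a signal on the scale of counts per gene, held 23310 genes with a total count of at least 2. In each of the 6 libraries these values equalled the counts divided by 1 size factor. A deposited table of the authors' comparison held log2 fold changes, p-values and adjusted p-values for 462 genes. Every per-sample column matched the labels of 1 sample.

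Library totals were 16788467, 17106509 and 22514707 counts for normoxic-EV replicates 1 to 3 and 16751665, 19739483 and 23422328 for hypoxic-EV replicates 1 to 3. Pairs of libraries of a group were compared by a chi-square over genes with at least 20 counts in the pair. The chi-square per degree of freedom ran from 2.72 to 5.84, so each pair differed by more than counting noise alone, which libraries prepared separately from 1 culture would also do. Each library was counted as its own sample because the labels list it as one. A count of 3 in a library, the limit that a count of 0 allows, came to between 0.129 and 0.179 CPM. Such limits cover counting error only, because reads without molecular identifiers are not independent molecules.

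The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10 and minimum total count of 15, which left 13303 genes. Libraries were scaled by TMM, and hypoxic-EV was compared with normoxic-EV by the quasi-likelihood F-test, which is two-sided, with Benjamini-Hochberg adjustment over all genes tested. A gene was called changed at an adjusted p under 0.05. CPM values are TMM-scaled, values after ± are SD over 3 libraries unless SE is written, and the SE of a log2 fold change is its size divided by the square root of the F statistic. The common biological coefficient of variation was 0.0489.

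Before the data were examined, 30 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Of the symbols in these lists and in 5 added after the data were seen, 855 matched a symbol of the count table, 2 matched by gene identifier, 8 by a synonym, and 1, a second name of a gene already listed, matched nothing. The lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment. The camera test was repeated with a correlation estimated per list, and fry was run beside it. Lists with under 3 tested members had no list test, which left 29. Fry asks whether the genes of a list move on balance in 1 direction and does not compare the list with other genes. The lists cover pro-inflammatory cytokines and M1 markers, chemokines, M2 markers and resolution genes, NF-kB signalling, type I interferon response, antigen presentation, HIF targets, glycolysis, nuclear-encoded and mitochondrially encoded oxidative phosphorylation, ribosomal proteins, cholesterol biosynthesis, lipid handling, the integrated stress, unfolded protein, heat shock and NRF2 responses, G1/S, G2/M, p53 targets, immediate early genes, JAK-STAT signalling, lysosome and phagocytosis, macrophage identity, osteoclast genes, matrix proteases, growth factors, and markers of stromal cells, of neutrophils and dendritic cells, and of lymphocytes.

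Genes were named in 3 ways. The first took, among called protein-coding genes with at least 5 CPM in the higher group and no overlap between the groups, the 12 highest and the 12 lowest log2 fold changes. The second took up to 4 changed members of lowest p from each list that passed camera or had at least 3 changed members, and the member of lowest p from a list with none. The third took 10 macrophage activation markers whatever their values. Any other gene named was chosen after its values were seen.

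The scripts were tested on simulated counts for the same 2 groups of 3, with the libraries' own means, sizes and dispersions. In the comparison of hypoxic-EV with normoxic-EV, simulated over 13133 genes, edgeR recovered 74.2% of 97 genes changed by 0.5 on the log2 scale and 90.7% of 97 changed by 1, with 11 false calls among 171. Camera, simulated over 13303 genes, recovered 3 of 3 lists moved by 0.5 and called 0 lists when none was moved. Those simulated genes vary independently of each other, unlike real ones. In the gene simulation 200 genes were changed, equally in both directions, while 44.2% of genes were called in the real comparison. The rates of recovery and of false calls may therefore not hold for the real comparison.

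The alternatives were RLE, upper-quartile or total-count scaling, no filter on counts, a filter of at least 1 CPM in 3 samples, DESeq2 1.42.0, limma-voom, the replicate number as a block, limma-trend on log2(FPKM + 1) with at least 0.5 FPKM in 3 samples, the same with a pseudocount of 0.1 or with no filter, protein-coding genes alone, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and leaving out each replicate. A correction for gene length and GC content, by splines with 4 degrees of freedom per library, and a test against a fold of 1.2 were added after the data were seen. Gene length came from the ratio of count to FPKM in the deposited tables, and GC content from GENCODE transcripts of the preceding mouse build, matched by gene identifier for 98.3% of tested genes, with the median for the rest. Annotation terms among the changed genes were planned and not analysed here, because the tables used pair genes with no terms. Positions are those of the deposited tables.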

Results

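The dataset measured poly(A) RNA in RAW 264.7 cells, a mouse macrophage line, that had been stimulated with lipopolysaccharide, a bacterial cell wall component that induces an inflammatory state, and then treated with extracellular vesicles (EVs) shed by tendon stem cells. The vesicles came either from cells kept in normoxia (normoxic-EV, 3 samples) or from cells preconditioned in hypoxia (hypoxic-EV, 3 samples). The comparison asks how macrophage transcripts differ with the oxygen history of the cells that shed the vesicles. Library totals ran from 16751665 to 23422328 counts, with a mean of 18.8 ± 3.21 M counts in normoxic-EV and 19.967 ± 3.31 M counts in hypoxic-EV (SD, n = 3, two-sided exact permutation p = 0.7). Libraries of a group had Spearman correlations of log2 CPM across genes between 0.9961 and 0.9972, and libraries of different groups between 0.9845 and 0.9879. The first principal component of the 500 most variable genes held 74.7% of their variance and placed the normoxic-EV libraries between -15.63 and -14.24 and the hypoxic-EV libraries between 13.40 and 15.99. Labels did not say whether samples came from separate cultures, so p-values measure the spread between these samples, which may be technical.

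In macrophages given hypoxic-EV, 17 of 20 pro-inflammatory genes were lower than in macrophages given normoxic-EV, and 38 of 38 mitotic genes, 17 of 19 glycolysis genes and 17 of 26 HIF targets were higher. Camera called each of these 4 lists, and the adjusted p of each was 0.0823 with an estimated correlation. Of 13303 genes tested, 5877 (44.2%) changed by edgeR's quasi-likelihood test at an adjusted p under 0.05, with 3023 higher and 2854 lower in hypoxic-EV. Most changes were small: the median absolute log2 fold change of the called genes was 0.364, and 219 called genes were at least 2-fold higher and 316 at least 2-fold lower. The values of the groups did not overlap in 52.8% of tested genes, where chance gives 10% for 3 against 3. Among protein-coding genes, 2806 were higher and 2584 lower. Called long noncoding RNAs were mostly lower (62 higher, 197 lower) and called processed pseudogenes mostly higher (119 higher, 35 lower). The median log2 fold change of all tested genes was -0.001.

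Decreases were ranked among called protein-coding genes with at least 5 CPM in the higher group and no overlap between the groups. The cytokine genes Csf2, Il6 and Il12b fell most, followed by Marcks, which is not a cytokine gene. Csf2, encoding the growth factor GM-CSF, fell from 6.05 ± 0.458 CPM to 0.455 ± 0.141 CPM (SD, n = 3), a log2 fold change of -3.68 (SE 0.227, edgeR adjusted p = 3.56e-11). Il6, encoding interleukin 6 (ENSMUSG00000025746, chromosome 5, 30218112 to 30224979, GRCm39), fell from 41.5 ± 2.74 CPM to 3.37 ± 1.03 CPM (log2 fold change -3.59, SE 0.124, edgeR adjusted p = 8.73e-15). Il12b and Il23a, which encode the subunits of interleukin 23, were 10.2-fold and 5.79-fold lower. The monocyte chemoattractant gene Ccl7 was 7.47-fold lower, and Marcks, which encodes a protein kinase C substrate at the plasma membrane, was 8.39-fold lower (20.4 ± 0.433 CPM to 2.42 ± 0.0698 CPM, n = 3). Hecw2, a ubiquitin ligase gene, Clec4a2, a C-type lectin receptor gene, Zfp811 and 4930438A08Rik were between 3.93-fold and 5.61-fold lower. Cd300ld3 and Cd300ld4 were 4.41-fold and 5.29-fold lower, but they belong to a cluster of similar genes whose reads may have been divided between copies.

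The largest increase among genes chosen in the same way was that of Prss46, a serine protease gene (ENSMUSG00000049719, chromosome 9, 110673574 to 110685590), which rose from 0.774 ± 0.116 CPM to 6.20 ± 0.524 CPM (SD, n = 3, 8.01-fold higher, SE of the log2 fold change 0.201, edgeR adjusted p = 1.28e-10). Hal, encoding the histidine-degrading enzyme histidine ammonia-lyase, was 5.15-fold higher at 23.2 ± 0.514 CPM. The myeloid receptor genes Treml4 and Trem1 were 4.40-fold and 4.15-fold higher, and the chemokine receptor gene Cxcr4 3.81-fold higher. Pmepa1 and Id1, which are known targets of TGF-beta and BMP signalling, were 4.23-fold and 3.62-fold higher. Adm, encoding the vasodilator peptide adrenomedullin, was 4.22-fold higher, and Igf1, encoding insulin-like growth factor 1, 3.88-fold higher. Mmp12, the macrophage elastase gene, and Ifitm1 were 3.49-fold and 3.48-fold higher. Ankrd37 was 3.58-fold higher, although it lies across from Ufsp2 on the other strand, whose total count was 1150% of its own, so its reads could not be separated from those of Ufsp2 with certainty.

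**Figure D1:**
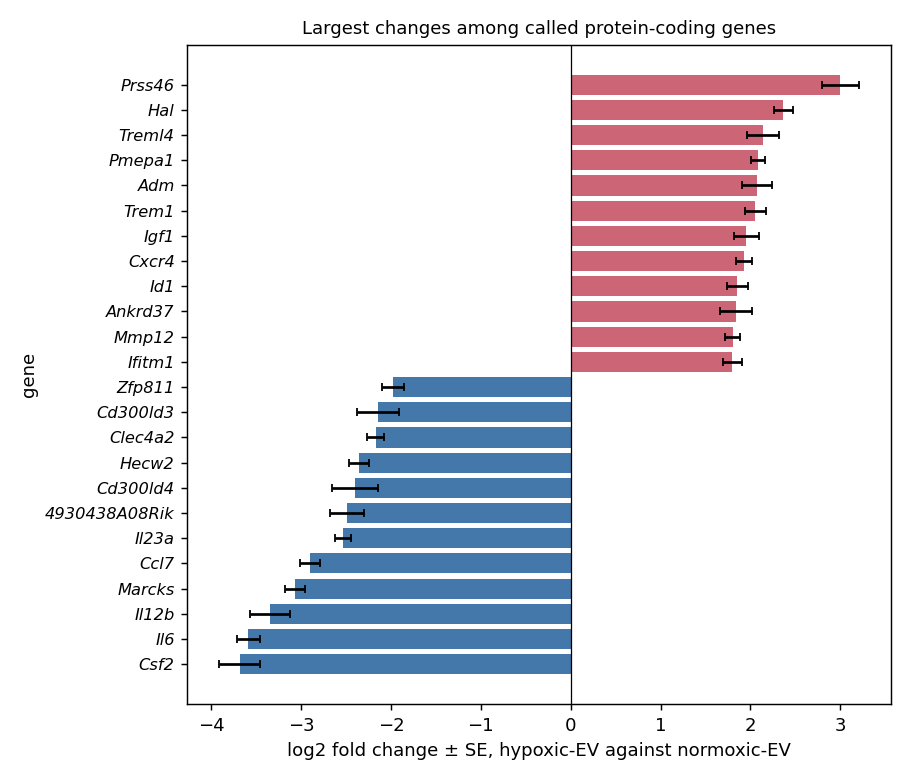
Log2 fold change (hypoxic-EV against normoxic-EV, bars) with its SE (error bars) for the 12 highest and 12 lowest called protein-coding genes with at least 5 CPM in the higher group and no overlap between groups. The decreases reach -3.68 for Csf2, and the increases start at 1.80 for Ifitm1.

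Pro-inflammatory genes were lower as a group. Of 20 tested members of the list of pro-inflammatory cytokines and M1 markers, 17 fell and 0 rose, with a median log2 fold change of -1.08 (camera adjusted p = 5.44e-13, adjusted p = 0.0823 with an estimated correlation). Ptgs2, which encodes the prostaglandin-synthesising enzyme cyclooxygenase 2, fell from 900.1 ± 30.4 CPM to 291 ± 7.11 CPM (SD, n = 3, log2 fold change -1.63, edgeR adjusted p = 1.51e-15). Lcn2, encoding the iron-sequestering protein lipocalin 2, was 3.59-fold lower. Tnf, encoding tumour necrosis factor, fell less, from 537 ± 17.8 CPM to 360.3 ± 26.9 CPM (log2 fold change -0.57, SE 0.0523, edgeR adjusted p = 1.44e-08), and Cd86, a costimulatory receptor gene, had a log2 fold change of -0.58 (SE 0.0583). Il1b was expressed at 5.82 ± 1.17 CPM and fell to 2.86 ± 0.314 CPM (SE of the log2 fold change 0.172, edgeR adjusted p = 7.19e-05). Nos2, encoding inducible nitric oxide synthase, stood at 56.6 ± 2.66 CPM in normoxic-EV and 56.8 ± 1.84 CPM in hypoxic-EV (log2 fold change 0.00, SE 0.0573, edgeR adjusted p = 0.971). The other members not called, chosen for mention after their values were seen, were Il18 (log2 fold change 0.17) and Osm (-0.08).

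Of 12 tested chemokine genes, 9 fell and 0 rose (median log2 fold change -1.15, camera adjusted p = 8.48e-07, adjusted p = 0.17 with an estimated correlation). Ccl3 fell from 2296 ± 114 CPM to 764 ± 47.3 CPM (SD, n = 3), and Cxcl2 and Ccl9 had log2 fold changes of -1.29 and -1.30. In the NF-kB list, which holds transcription factor subunits, inhibitors and targets of that pathway, 22 of 31 tested members fell and 2 rose (median -0.32, camera adjusted p = 1.83e-08, adjusted p = 0.0823 with an estimated correlation). Traf1, a signalling adaptor gene, was lower by a log2 fold change of -1.87 and Cflar, encoding an inhibitor of caspase 8 activation, by -0.97. Bcl2a1d and Bcl2a1b, anti-apoptotic genes of a family of near-identical copies, fell from 106 ± 8.78 to 52.9 ± 1.69 CPM and from 48.5 ± 3.50 to 21.3 ± 2.26 CPM (SD, n = 3), values that stay uncertain because reads may be divided between the copies.

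**Figure D2:**
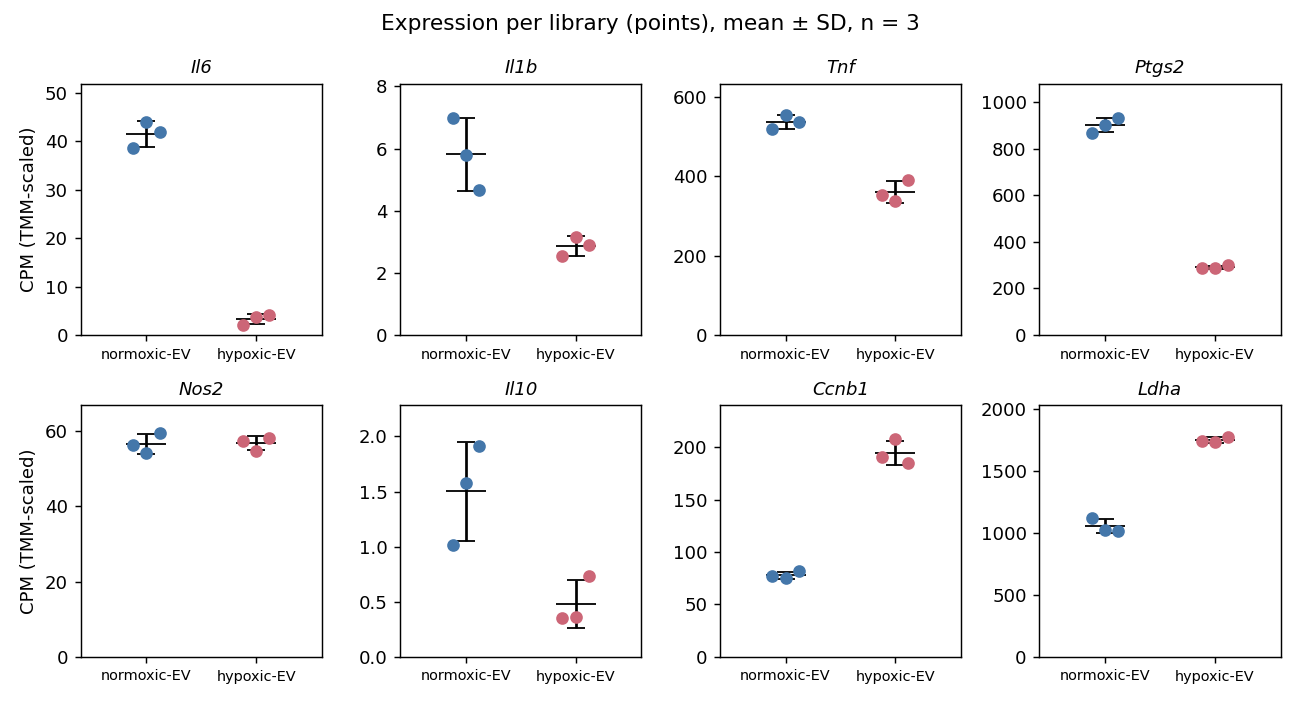
TMM-scaled CPM (vertical axis, linear, from 0) of 8 genes in each library of normoxic-EV and hypoxic-EV (points), with the mean and SD of 3 libraries (bars). Il6, Il1b, Tnf, Ptgs2 and Il10 lie lower in each hypoxic-EV library than in each normoxic-EV library, Ccnb1 and Ldha lie higher, and Nos2 overlaps at means of 56.6 and 56.8 CPM.

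Markers of alternative activation moved in both directions. Of 18 tested members of the list of M2 markers and resolution genes, 4 rose and 5 fell (median -0.01, mean 0.07, camera adjusted p = 0.88). Fry, which does not compare a list with other genes, called the list higher (fry adjusted p = 0.0162). The median ran from -0.017 to 0.004 without each library in turn, the latter without normoxic-EV replicate 3. Trem2, a lipid-sensing receptor gene, rose from 51.2 ± 1.16 CPM to 114 ± 6.61 CPM (SD, n = 3, log2 fold change 1.15, edgeR adjusted p = 7.58e-13). Stab1, a scavenger receptor gene, had a log2 fold change of 1.28, but it overlaps Nt5dc2 on the other strand, whose total count was 143% of its own. Il1rn, encoding the interleukin 1 receptor antagonist, fell by 1.08 on the log2 scale. Il10, encoding an anti-inflammatory cytokine, fell from 1.501 ± 0.452 CPM to 0.481 ± 0.217 CPM (log2 fold change -1.60, SE 0.344, edgeR adjusted p = 0.000679), and Tgfb1 had a log2 fold change of -0.29 (edgeR adjusted p = 9.35e-05). Mrc1, the mannose receptor gene, stood at 0.928 ± 0.134 and 1.18 ± 0.147 CPM (edgeR adjusted p = 0.337). Arg1 was below the count filter, with 28 counts in the normoxic-EV libraries and 17 in the hypoxic-EV libraries. Cd163 had 0 counts in each library, which allows up to 0.179 CPM in a single library.

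Macrophage identity genes also moved both ways, with 4 of 16 higher and 7 lower (median -0.10, camera adjusted p = 0.178). The median ran from -0.109 to 0.001 without each library in turn, the latter without hypoxic-EV replicate 2. Csf1r, the receptor gene for the macrophage growth factor M-CSF, rose from 174 ± 6.93 CPM to 352 ± 13.4 CPM (SD, n = 3, log2 fold change 1.02, edgeR adjusted p = 6.93e-13), with Hmgxb3 overlapping it on the other strand at 20.7% of its total count. Adgre1, which encodes the surface marker F4/80, and the Fc receptor genes Fcgr1 and Fcer1g had log2 fold changes of -0.80, -0.72 and -0.64. In the lysosome and phagocytosis list 9 of 34 members rose and 20 fell (median -0.18, mean -0.09, camera adjusted p = 0.0149, adjusted p = 0.488 with an estimated correlation). Its members of lowest p included Lipa, the lysosomal acid lipase gene, and Ncf1, an NADPH oxidase subunit gene, which rose by log2 fold changes of 0.67 and 0.66, and the proton pump gene Atp6v0a1 at -0.70. In the antigen presentation list 7 of 16 fell and 2 rose (camera adjusted p = 0.0434, adjusted p = 0.496 with an estimated correlation), with Cd74 at -0.67, Tap1 at -0.41, B2m at -0.30 and Ctss at 0.30. Tap1 overlaps Psmb9 on the other strand, at 31.5% of its total count. That call ended without normoxic-EV replicate 1 (camera adjusted p = 0.0892) and without hypoxic-EV replicate 2 (camera adjusted p = 0.112), within a range of 0.019 to 0.112 over the 6 replicates left out.

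Of 38 tested interferon response genes, 16 fell, 5 rose and 17 were not called (median -0.21, camera adjusted p = 0.0119, adjusted p = 0.418 with an estimated correlation). The checkpoint ligand gene Cd274 fell from 106 ± 11.7 CPM to 49.3 ± 1.99 CPM (SD, n = 3), Ifi204 and the guanylate-binding protein gene Gbp2 had log2 fold changes of -1.11 and -1.47, and Ifitm3 rose by 0.45. Ifi204 belongs to a family of similar genes, so its reads are uncertain. Of 26 JAK-STAT genes, 6 fell and 2 rose (camera adjusted p = 0.217), among them the kinase gene Jak2 at -0.74, the feedback inhibitor gene Socs3 at -0.51, Bcl6 at -0.43 and Il6ra at 0.31. Of 25 immediate early genes, 11 fell and 5 rose (camera adjusted p = 0.077), with Klf6 at -0.50, Atf3 at -0.52, Myc at -0.82 and Dusp5 at -0.44. Without hypoxic-EV replicate 1, camera called that list lower (adjusted p = 0.0211), within a range of 0.0211 to 0.263 over the 6 replicates left out.

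Hypoxia-response and glycolytic genes were higher with hypoxic-EV. Of 26 tested HIF targets, 17 rose and 3 fell (median 0.44, camera adjusted p = 8.84e-07, adjusted p = 0.0823 with an estimated correlation). Bnip3, a mitophagy receptor gene, rose from 91.3 ± 5.15 CPM to 182 ± 1.21 CPM (SD, n = 3, edgeR adjusted p = 1.45e-12). Egln3, encoding an oxygen-sensing prolyl hydroxylase, and Car12, a carbonic anhydrase gene, had log2 fold changes of 1.39 and 1.36, and the adenylate kinase gene Ak4 0.96. Slc2a1, Vegfa and Hilpda, named after their values were seen, were not called, at log2 fold changes of -0.03, -0.02 and -0.02. Of 19 glycolysis genes, 17 rose and 1, Eno2 (named after its values were seen), fell (median 0.60, camera adjusted p = 7.34e-12, adjusted p = 0.0823 with an estimated correlation). Pkm, the pyruvate kinase gene, rose from 4253 ± 88.5 CPM to 7183 ± 77.3 CPM, and Ldha, the lactate dehydrogenase gene, from 1056 ± 55.6 CPM to 1752 ± 21.4 CPM (n = 3, log2 fold change 0.73, edgeR adjusted p = 9.34e-11). Hk1 and Pfkl, which encode hexokinase and phosphofructokinase, had log2 fold changes of 0.81 and 0.95.

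The 13 mitochondrially encoded genes each rose (median 0.72, camera adjusted p = 4.85e-10, adjusted p = 0.0935 with an estimated correlation). The share of all counts that fell on the mitochondrial genome, genes outside this list included, was 2.17 ± 0.054% in normoxic-EV and 2.99 ± 0.075% in hypoxic-EV (SD, n = 3, two-sided exact permutation p = 0.1, the smallest that 3 against 3 allow). The complex I gene mt-Nd1 rose from 1253 ± 48.3 CPM to 2433 ± 57.0 CPM, and mt-Nd2, mt-Nd4 and mt-Cytb had log2 fold changes of 0.79, 0.60 and 0.54. Of 47 nuclear genes of oxidative phosphorylation, 25 rose and 1 fell, by less (median 0.14, camera adjusted p = 3.9e-05, adjusted p = 0.435 with an estimated correlation). They included the complex I gene Ndufv2 at 0.59, the succinate dehydrogenase genes Sdha and Sdhb at 0.42 and 0.41, and the ATP synthase gene Atp5c1 at 0.41. Of 75 cytoplasmic ribosomal protein genes, 38 rose and 4 fell (median 0.14, camera adjusted p = 1.31e-05, adjusted p = 0.435 with an estimated correlation), led by Rpl3 at 0.58, Rpl37a at 0.64, Rpl23a at 0.49 and Rpl6 at 0.40. Ribosomal protein genes have many processed pseudogenes that may share their reads.

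Each of the 38 tested genes of the G2/M and mitosis list rose (median 1.02, camera adjusted p = 7.6e-39, adjusted p = 0.0823 with an estimated correlation). Ccnb1, encoding the mitotic cyclin B1, rose from 77.6 ± 3.51 CPM to 194 ± 11.7 CPM (SD, n = 3, log2 fold change 1.32, SE 0.0542, edgeR adjusted p = 8.76e-14). Ccnb2 and Ube2c, which encode another mitotic cyclin and a ubiquitin-conjugating enzyme of mitotic exit, had log2 fold changes of 1.35 and 1.58. Cdc20 had 1.30 but overlaps Elovl1 on the other strand, whose total count was 120% of its own. Of 34 genes of G1/S and DNA replication, 31 rose and 1 fell (median 0.42, camera adjusted p = 8.54e-12, adjusted p = 0.0953 with an estimated correlation). The ribonucleotide reductase gene Rrm2 rose from 163 ± 5.92 CPM to 266 ± 4.32 CPM, and the ligase gene Lig1 and the replicative helicase genes Mcm6 and Mcm7 had log2 fold changes of 0.65, 0.62 and 0.57. Mcm7 overlaps Cops6, at 44.7% of its total count. Of 19 p53 targets, 11 fell and 3 rose (median -0.23, camera adjusted p = 0.000736, adjusted p = 0.117 with an estimated correlation). Plk2, Gadd45a and Gadd45b, stress-induced growth regulators, had log2 fold changes of -1.09, -1.04 and -1.04, and Sesn2 had -0.40.

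Stress-response lists differed in direction. In the unfolded protein response list 14 of 20 fell and 2 rose (median -0.26, camera adjusted p = 1.15e-05, adjusted p = 0.298 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, fell from 3477 ± 97.4 CPM to 1832 ± 48.8 CPM (SD, n = 3, log2 fold change -0.92, edgeR adjusted p = 1.56e-12), and Selenos, the stress sensor gene Ern1 and Dnajb9 had log2 fold changes of -0.68, -0.51 and -0.49. In the heat shock list 9 of 14 rose and 0 fell (median 0.22, camera adjusted p = 0.000208, adjusted p = 0.418 with an estimated correlation), with the cytosolic chaperone genes Hspa8, Hsp90ab1, Hsp90aa1 and Dnaja1 at 0.75, 0.54, 0.34 and 0.35. Dnaja1 overlaps Smu1 on the other strand, at 78.6% of its total count. In the NRF2 list 11 of 19 rose and 3 fell (median 0.30, camera adjusted p = 0.000931, adjusted p = 0.34 with an estimated correlation). Hmox1, the haem oxygenase gene, rose from 775 ± 38.5 CPM to 1209 ± 60.3 CPM, and Pgd, Gclm and Cat, of the pentose phosphate pathway, glutathione synthesis and peroxide removal, had log2 fold changes of 0.78, 0.79 and 0.71. Of 23 ATF4 targets, 9 fell and 5 rose (camera adjusted p = 0.19). Nupr1 and Ppp1r15a, a phosphatase subunit gene of the stress response, fell by 1.01 and 1.22 on the log2 scale, while Pck2 rose by 0.77. Ddit3 had -1.08 but overlaps Mars1, whose total count was 198% of its own.

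Lipid genes moved in both directions. Of 25 cholesterol biosynthesis genes, 6 fell and 3 rose (camera adjusted p = 0.2), with the sterol oxidase gene Msmo1 at -0.39 and Hsd17b7 at -0.38. Fdft1 had -0.43 but overlaps Ctsb on the other strand, whose total count was 11900% of its own. Of 18 lipid handling genes, 6 rose and 5 fell (camera adjusted p = 0.494). Cpt1a, encoding the enzyme that controls fatty acid entry into mitochondria, rose from 23.6 ± 0.898 CPM to 68.8 ± 1.80 CPM (SD, n = 3, log2 fold change 1.54, edgeR adjusted p = 6.98e-14), the lipase gene Lpl rose by 0.59, and the cholesterol exporter gene Abcg1 had -0.41. Pltp had 0.82 but overlaps Ctsa, whose total count was 3290% of its own.

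Among 13 osteoclast genes, 4 rose and 5 fell (median -0.08, from -0.121 to 0.088 without each library in turn, the highest without normoxic-EV replicate 1, camera adjusted p = 0.965), with the carbonic anhydrase gene Car2 at 0.82 and Atp6v0d2 and Clcn7 at -1.07 and -0.38. Among 14 matrix proteases and their inhibitors, 4 rose and 6 fell (camera adjusted p = 0.859), and the sign of the median of -0.001 was not firm: it was 0.003 with the upper-quartile scaling and ran from -0.035 to 0.111 without each library in turn, the highest without normoxic-EV replicates 1 or 2. Plau, the urokinase gene, rose from 366 ± 14.98 CPM to 686 ± 24.0 CPM (SD, n = 3, log2 fold change 0.91, edgeR adjusted p = 2.79e-12), and Adamts1 and the gelatinase gene Mmp9 had log2 fold changes of -1.53 and -1.22. Among 15 growth factor and angiogenesis genes, 4 rose and 3 fell (median 0.14, camera adjusted p = 0.859). The median ran from 0.084 to 0.133 without each library in turn, the lowest without hypoxic-EV replicate 2. Igf1 was 3.88-fold higher, Spp1, encoding osteopontin, fell from 17410 ± 501 CPM to 10470 ± 223 CPM, and Vegfc had a log2 fold change of -0.94.

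Markers of other cell types were sparse. Of the stromal and tendon stem cell markers, 3 of 27 passed the count filter and 0 changed by edgeR, also at an unadjusted p under 0.05 (median -0.06, from -0.154 to 0.015 without each library in turn, the latter without normoxic-EV replicate 3, camera direction up, camera adjusted p = 0.965), the lowest p being that of Acta2 at 2.37 ± 0.281 and 2.98 ± 0.639 CPM (SD, n = 3, edgeR adjusted p = 0.18). Of the neutrophil and dendritic cell markers, 3 passed the filter and 1, S100a8 (named after its values were seen), fell (camera adjusted p = 0.19). Of the lymphocyte markers, 2 passed the filter, too few for a list test, and both, Cd79a and Ighm (named after their values were seen), rose, with log2 fold changes of 1.36 and 0.16.

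Over the 30 lists, 446 of 657 tested members changed, 263 higher and 183 lower. Among all tested genes 44.2% changed, and among protein-coding genes 47.5%, so a count of changed members alone does not set a list apart. Adjusted over the list alone, the counts differed from those above only in oxidative phosphorylation (26 higher), ribosomal proteins (39 higher), the unfolded protein response (15 lower), G1/S (32 higher), lysosome (21 lower) and matrix proteases (7 lower). Camera called 17 of 29 lists, 9 higher and 8 lower. With an estimated correlation it called 0, with 8 lists at an unadjusted p under 0.05, and fry called 26. Fry left only the osteoclast, growth factor and stromal marker lists uncalled. It thus called lists that camera did not, such as M2 markers, macrophage identity and JAK-STAT. Camera also called between 7 and 14 lists in the other 9 divisions of the 6 libraries into groups of 3, where edgeR called 0 genes. Each of those divisions mixed the treatments in unequal numbers, so part of their difference remained between groups and part widened the spread within them. Neither count is therefore a measure of false calls. The median had another sign than the mean and the camera direction for the M2 list and for the stromal markers. The direction of fry went against that of camera for the osteoclast, matrix protease and growth factor lists. Fry called only the matrix proteases of these (fry adjusted p = 0.0219, direction up), and not the osteoclast (0.737) or growth factor genes (0.553).

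**Figure D3:**
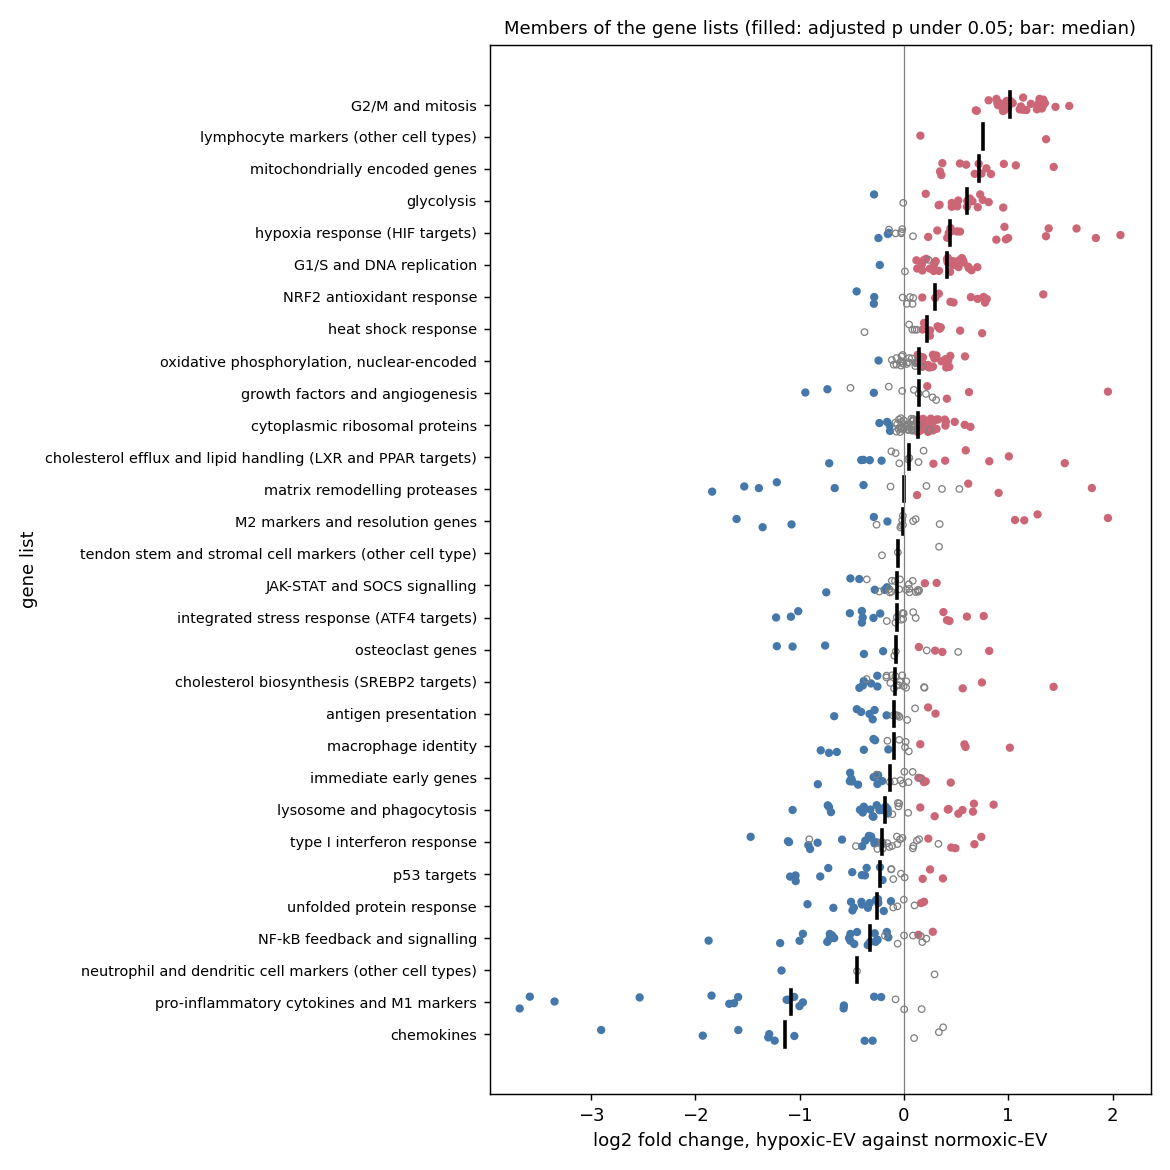
Log2 fold change (hypoxic-EV against normoxic-EV, horizontal axis) of each tested member of the 30 gene lists (rows, ordered by median). Filled points are members with an edgeR adjusted p under 0.05 (red higher, blue lower), open points are not called, and black bars mark medians, from -1.15 for chemokines to 1.02 for G2/M and mitosis.

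The authors' deposited table of their own comparison held 462 genes, 195 higher and 267 lower, of which 384 were protein-coding. In the authors' deposited table the smallest absolute log2 fold change was 1.001 and the largest adjusted p 0.0491. Of the 462 genes in the authors' deposited table, 451 were tested here, and edgeR called each of the 451 with the same sign. The other 11 had too few counts to be tested. DESeq2 run here gave the log2 fold change of the authors' deposited table for each of the 462 genes within a tolerance of 1e-06. It called 451 of the 462 and gave 11 no adjusted p, so the calls were not fully reproduced. By DESeq2 run here, 454 genes had an adjusted p under 0.05 and an absolute log2 fold change above 1. Of these, 451 were in the authors' deposited table. By edgeR, 535 genes had an adjusted p under 0.05 and an absolute log2 fold change above 1, and 447 of them were in the authors' deposited table.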

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

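The correction for gene length and GC content and the test against a fold of 1.2 were chosen after seeing the data, and the other alternatives before. The count of 5877 changed genes stayed within 1.5 times under the other scalings, filters, tools, corrections and the stricter adjusted p, from 4156 (limma-trend on unfiltered FPKM) to 6425 (length and GC correction), and from 4993 to 5778 without each replicate in turn (2547 to 3014 higher, 2390 to 2764 lower). DESeq2 called 4887 genes, 4873 of them among the 5877. A test against a fold of 1.2 called 2215 (1134 higher, 1081 lower), and a log2 limit of 1 left 535 (219 higher, 316 lower), fewer by construction since most changes were small. No scaling moved the median of all genes by more than 0.004. Camera's 17 lists (9 higher, 8 lower) became 0 (0 higher, 0 lower) with an estimated correlation and 26 (14 lower) with fry, which does not compare a list with other genes, and 16 to 18 without each replicate. Changed list members numbered 396 to 445 without each replicate, against 446.

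Whether the replicate numbers pair the samples stays open. Deviations of same-numbered libraries correlated at -0.011, -0.105 and -0.097, and no sample correlated best with its own number. The second principal component (7.61% of variance), however, ordered the replicate numbers alike in both groups. Replicates 1, 2 and 3 lay at -4.02, 4.70 and -0.66 in normoxic-EV and at -7.03, 7.21 and -0.20 in hypoxic-EV. With the replicate number as a block, 5662 genes were called (2910 higher, 2752 lower).

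Of 128 called named genes, 121 kept their sign and call in each alternative run on them. The other 7 lost the call in 8 fits, none reversing. Nos2, not called, changed sign with RLE factors (-0.001), the length and GC correction (-0.037), and without normoxic-EV replicate 2 (-0.032) or hypoxic-EV replicates 1 (-0.004) or 3 (-0.013), in a range of -0.032 to 0.044 without each replicate. Among lists not called by camera, direction reversed for osteoclast genes with fry (median -0.078) and without normoxic-EV replicate 1 (0.088), replicate 2 (0.045) or hypoxic-EV replicate 2 (-0.029; range -0.121 to 0.088), for proteases (-0.001) and growth factors (0.141) with fry, and for stromal markers with the length and GC correction (-0.095) and without normoxic-EV replicate 1 (-0.154) or hypoxic-EV replicate 3 (-0.091; range -0.154 to 0.015). Of the reversals with fry, only that of the proteases was a fry call (fry adjusted p = 0.0219). The cause of the reversals was not tested. Enrichment of annotation terms was not run. Depth limits genes such as Arg1 and Cd163, with at most 13 and 0 counts in a library.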

Other observations

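The 5 lists of this part were written after the table of all genes had been seen, and the tests of these lists, of length and GC content, of tendon cell RNA, of pairs of libraries with larger normoxic-EV totals, and of the share of abundant genes were chosen after results had been seen. Targets and components of TGF-beta and BMP signalling were higher with hypoxic-EV: of 13 tested, leaving out Pmepa1 and Id1, 10 rose and 2 fell (median 0.61, camera adjusted p = 0.000118, adjusted p = 0.0547 with an estimated correlation). Smad7 and Smad6, which encode inhibitors of these pathways, rose from 9.25 ± 0.808 to 18.4 ± 0.536 CPM and from 6.92 ± 1.08 to 15.5 ± 1.70 CPM (SD, n = 3), Id3 had a log2 fold change of 0.99, and Id2 and Tgif1 fell by 0.32 and 0.29 on the log2 scale, while Tgfb1 itself fell. Fatty acid oxidation genes were also higher: of 16 tested without Cpt1a, 10 rose and 1 fell (median 0.26, camera adjusted p = 0.0017, adjusted p = 0.0547 with an estimated correlation), among them Hadh (0.64), Acaa2 (0.58) and Acads (0.52). As both lists were written after the values had been seen, their p-values do not test whether signalling or metabolism differed.

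By camera, the other 3 added lists gave no direction that held. Fry called the inflammasome list lower (fry adjusted p = 0.000786) and did not call iron handling genes without Fth1 (fry adjusted p = 0.251). It also called the myeloid surface receptors lower when those already named were left out (fry adjusted p = 0.00127). Among 11 inflammasome genes 5 fell and 3 rose (median 0.02, mean -0.13, camera direction down, camera adjusted p = 0.217), with a median of -0.018 to 0.064 without each library in turn, negative without hypoxic-EV replicate 2: Casp4 fell from 85.3 ± 4.06 to 37.3 ± 1.002 CPM and Nlrp3 from 225 ± 10.7 to 131 ± 8.06 CPM (SD, n = 3), while Gsdmd and Nlrc4 rose by 0.38 and 0.56 on the log2 scale. Among 13 iron handling genes without Fth1, 4 fell and 3 rose (median -0.01, camera adjusted p = 0.504), with the iron exporter gene Slc40a1 at 0.52 and the importer gene Slc11a2 at -0.60. The median ran from -0.048 to 0.035 without each library in turn and was positive without normoxic-EV replicate 3 (0.035) or hypoxic-EV replicate 1 (0.013). Fth1 itself fell from 10540 ± 318 to 7700 ± 279 CPM (log2 fold change -0.45, edgeR adjusted p = 1.3e-07). With Fth1 included, 5 iron handling genes fell and 3 rose (camera adjusted p = 0.265). Among 30 myeloid surface receptors 10 rose and 14 fell (camera adjusted p = 0.265). Without the 6 already named, 5 of which had risen, 5 rose and 13 fell (camera adjusted p = 0.00358, adjusted p = 0.203 with an estimated correlation), so the call rests on which genes are left out and settles no shared direction. Cx3cr1 rose from 16.5 ± 0.227 to 56.9 ± 4.57 CPM and Ccr1 fell from 120 ± 7.14 to 41.8 ± 4.81 CPM.

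Mitotic genes were higher and pro-inflammatory genes lower with hypoxic-EV. After a correction for gene length and GC content the median of the mitosis list was 1.03 (1.01 to 1.06 without each library in turn) and that of the pro-inflammatory list -1.03 (-1.10 to -0.92), which argues against such a trend as the whole cause. After thinning every library to the smallest total and leaving out the 20 most abundant genes the medians were 1.02 (0.998 to 1.049) and -1.12 (-1.12 to -1.05), but library totals overlapped between the groups, so the thinning had little to remove. In 2 choices of 2 libraries per group the normoxic-EV totals were the larger on average (19.7 and 19.8 M counts against 18.2 M). There the medians were 1.035 and 1.04 for mitosis and -1.075 and -1.08 for the pro-inflammatory list. The signs held with the difference in totals reversed, which argues against that difference as the whole cause. The choices shared libraries, so they are not independent, the totals differed little, and each fit was already scaled by TMM. The share of counts in those 20 genes was 10.65 to 10.86% in normoxic-EV and 10.32 to 10.47% in hypoxic-EV, which can shift all other genes by at most 0.009 on the log2 scale, and argues against abundant genes as the cause. Different cell density or handling of the cultures, and the vesicle treatment that the design names, stay open and untested.

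HIF targets and glycolytic genes were higher with hypoxic-EV. Transcripts abundant in tendon cells (Col1a1, Col1a2, Col3a1, Sparc, Bgn, Dcn and Lum) summed to at most 0.00365% of the gain of the glycolysis list in a hypoxic-EV library, and the highest, Dcn, reached 0.41 CPM in any library, which argues against whole RNA of mouse tendon cells carried along with the vesicles. The species of the tendon stem cells is not given and only counts of mouse genes were used, so RNA of another species, and RNA that vesicles carry in other proportions, stay open. After the length and GC correction the medians were 0.55 for glycolysis (0.54 to 0.57 without each library) and 0.44 for HIF targets (0.43 to 0.46), which argues against that trend as the whole cause. An effect of the vesicles and a difference in oxygen, density or medium between cultures cannot be separated by this design.

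Called processed pseudogenes were mostly higher and called long noncoding RNAs mostly lower. The 554 noncoding RNAs with no changed coding gene within 10 kb had a median log2 fold change of -0.17 (95% bootstrap interval -0.23 to -0.13). That argues against following a changed coding neighbour as the whole cause. The 438 with such a neighbour had a median of -0.20, with 30 called higher and 78 lower. Their direction was not compared with that of the neighbour, so following stays open for them. Called coding genes matched on expression were lower in 57.1% of cases (48.3 to 65.6% over 1000 draws) against 76.1% of the 259 called noncoding RNAs and 47.9% of all called coding genes, which argues against low expression as the whole cause. Across 138 pseudogenes with a tested parent gene, the 2 log2 fold changes had a Spearman's rho of 0.638 (95% bootstrap interval 0.517 to 0.738), and 29 of 34 called ones moved with a parent called the same way, so reads shared with the parent may contribute. The interval takes the pseudogenes as independent, although several may share a parent gene, so it may be too narrow. As only 22.1% of the called pseudogenes had a tested parent gene, the sharing of reads stays open for the rest.

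The 6 libraries can be divided into 2 groups of 3 in 10 ways, too few for a share under 0.05. Every division but the real one mixed the treatments in unequal numbers, so its calls do not count false calls. The real division gave 5877 changed genes and the highest other 0, so the 1 of the 10 that gave as many was the real division itself. For the lists, the real division gave 17 by camera and the highest other 14, so the 1 of the 10 was again the real division.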
